A study of Mus musculus with 49 samples.

How the data were processed

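The series holds 49 libraries from wild-type (WT) mice and mice with loss of Pten. ATAC-seq, which marks accessible chromatin by transposase insertion, was deposited for 24 libraries, each made per the labels from 1000 sorted bone marrow cells. Bulk RNA-seq of poly(A) RNA was deposited for 12 libraries of sorted bone marrow prepro-B cells, and plate-based single-cell RNA-seq for 13 libraries of Pten-null bone marrow and thymus populations. Groups and replicate numbers were taken from the sample titles. The columns of the expression table that are not WT are named TALL. They were matched to the titles by CD38 fraction and replicate number, and their genotype by elimination, since Pten-null is the only other genotype among these samples. In all, 0 sample columns stayed unmapped. The name TALL is not explained in the labels used here, so differences of these libraries from WT other than loss of Pten are not excluded. The labels do not say whether replicates came from separate animals, so limma p-values of genes measure the spread between these libraries, which may be technical. Fisher's exact tests on ATAC regions count regions as independent, and their p-values measure no spread between libraries.

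FastQC, Trim Galore, Bowtie2, TopHat, Cuffdiff and HTSeq and the genome build mm10 are named, without versions or roles, per the submitters' processing notes. For bulk RNA-seq the authors deposited FPKM values (fragments per kilobase of transcript, scaled for library size) for 54141 entries; the library-size method behind them is not given in the sources used here. For ATAC-seq the authors deposited a peak list per library, with MACS2 in the peak names, and each peak carries a fold enrichment over background and the −log10 of a p-value and a q-value, per the file headers and the standard layout of such lists. These peak values are the authors' own and were used only to rank or filter peaks within a list. Read counts over shared regions were not used here. For single cells the authors deposited counts per gene and well. The count files are named for molecular identifiers, although the totals per well, with medians of 140533 to 1055747, are high for molecules, so a count may be a read. Intervals on counts cover counting error only, and each count is treated as independent in them. Counts of paralogs and of immunoglobulin segments are uncertain, since the treatment of reads shared between near-identical copies is not given in the sources used here.

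FPKM values were analysed as log2(FPKM + 1), which understates the change of low genes. Of 54051 symbols, after 90 duplicates were dropped, the 13738 genes with an FPKM of at least 1 in at least 3 libraries were tested. Group means over all 12 libraries were fitted with limma 3.58.1 (moderated linear model with trend) in R 4.3.3, and 5 contrasts were taken: Pten-null against WT in each CD38 fraction, CD38high against CD38low in each genotype, and the interaction of genotype and fraction. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Tests with edgeR on counts had been written down as the first choice for count tables and were replaced, as planned for normalized values, because the table holds FPKM. In simulated data for the CD38low genotype contrast over 13738 genes, 69.0% of genes changed by a log2 of 1 and 95.7% of genes changed by a log2 of 2 were called, and 3.71% of the calls were false. Genes varied independently in that simulation, without deviations shared by a library, so it does not give the rate of false calls in these data. FPKM tables give no read totals. The spacing of FPKM values under 0.1 put the depth of the libraries between 0.892 and 1.26 times that of WT CD38low replicate 1, with 13.7% to 37.2% of such genes at the most frequent ratio, and whole reads were not recovered from them. FPKM totals ran from 531855 to 721091 per library.

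22 gene lists (lineage markers, markers of other cell types, signalling and metabolic programmes), the rule for named genes, the tests and most alternatives were fixed before the data were examined. Lists were tested with limma's camera at its preset inter-gene correlation, with the adjustment over the 22 lists of a contrast, and repeated with an estimated correlation and with fry. Named genes were Pten, Spi1 and Cd38; the 8 largest rises and 8 largest falls per contrast among called genes whose group values did not overlap, with a mean FPKM of at least 1 in the higher group, without predicted genes and receptor segments; and up to 4 members with the smallest p of each list that passed camera or had 3 or more called members. Replicate numbers are shared by all groups. Deviations of same-numbered libraries from their group means correlated across genes in the CD38high genotype comparison (0.197, 0.225 and 0.395), in the WT fraction comparison (0.29, 0.419 and 0.356) and in the Pten-null fraction comparison (0.17, 0.27 and 0.296), so the numbers pair these libraries, on the evidence of the data. All values are from the fit without the replicate block, as planned, and where the numbers pair the libraries, the blocked value stands beside a result whose call it changes or whose count it moves by over 1.5 times.

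Peaks on the 19 autosomes and chromosome X were merged per comparison into regions (overlap of at least 1 bp). A region was gained when every library of the compared group and no library of the base group had a peak in it, and lost in the reverse case. Peaks were called per library, and the number called differs between libraries, so each comparison was repeated with the same number of peaks per library. In a simulation in which each library missed 2% of peaks at random, 191 of 200 gained and 188 of 200 lost regions were recovered, with 0 false ones. Real libraries differed more: CD38low prepro-B pairs of the same genotype had a Jaccard overlap (shared over combined) of 0.612 to 0.766. The simulation therefore does not give the rate of false regions in these data. Genes were placed from a RefSeq table of GRCm38.p6 (mm10), with 21631 protein-coding genes; because transcription start sites were not used here, a region was assigned to genes whose body lies within 50 kb, which replaced the planned nearest start site. Exons and introns were not used here. Up to 5 gained and 5 lost regions per comparison with the highest mean −log10 p near list genes are named. Each is named by its nearest list gene, so a gene outside the lists may lie closer. Gene sets near gained or lost regions were tested with camera on the RNA contrast of the same fraction. In simulated data 20 of 20 shifted sets and 0 of 20 unshifted sets passed. The simulated genes varied independently of each other, so this does not show how often correlated genes pass without a shift. The planned motif test was not run, because it needs the genome sequence.

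Wells with at least 10000 counts and at least 1000 genes were kept. Counts were summed per library, and list shares carry exact Clopper-Pearson 95% intervals and folds exact Poisson 95% intervals; a fold against 0 counts uses a floor of 3 counts over the group. In 500 simulated draws the intervals covered the true value in 97.0% of shares and 96.2% of folds. Each population has 1 library except prepro-B cells with 2, so no test was made. Each well was sorted to hold 1 cell, no doublet caller was run and wells were not clustered. Named genes were fixed markers and the 8 largest and 8 smallest folds of prepro-B cells against common lymphoid progenitors and against DN3 cells, with at least 100 counts and the same direction in both prepro-B libraries. Classes of prepro-B wells by list share, and how far their Spi1 and Igll1 levels rest on single wells, were added later. Profile genes of a class had at least 4 times the CPM of each other class, and genes as low in NK wells as Spi1 had a ratio of NK to all other wells no higher than that of Spi1, in both libraries and with at least 100 counts.

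Alternatives for RNA were no filter, an FPKM filter of 5, pseudocounts of 0.1 and 5, limma without trend, only the compared libraries, a replicate block and each library left out in turn; for peaks a −log10 q of at least 5, an overlap of 50%, equal peak numbers and each library left out; for the link of regions and genes a distance of 10 kb; for single cells other well filters, other weightings and a prepro-B library left out. Scaling to an equal trimmed mean, quantile normalization, an animal block within genotype, an estimated correlation, a replicate block and left-out libraries for the link, list tests near regions and scalings or left-out libraries for the list tests were added after seeing the data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.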

Results

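Chromatin accessibility, gene expression and single-cell expression were measured in blood-forming cells of WT mice and of mice that had lost Pten, the phosphatase that opposes PI3K signalling. The design asked how loss of Pten alters accessibility in stem and progenitor cells, and accessibility and expression in prepro-B cells, with the myeloid and lymphoid transcription factor PU.1 (encoded by Spi1) at its centre. ATAC-seq covered hematopoietic stem cells (HSC), lymphoid-primed multipotent progenitors (LMPP) and common lymphoid progenitors (CLP) with 2 libraries per genotype each, and CD38low and CD38high prepro-B cells with 3 libraries per genotype each. The 24 ATAC libraries held 58628 to 95236 peaks, which covered 35.9 to 60.1 Mb. Bulk RNA-seq covered CD38low and CD38high prepro-B cells with 3 libraries per genotype each. The 13 single-cell libraries came from Pten-null animals alone and kept 58 to 95 wells and 13023390 to 81629043 counts each. The number of reads behind the FPKM values is unknown. Replicate libraries correlated at 0.946 to 0.973 across genes.

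Pten was measured first, as the targeted gene. In CD38low prepro-B cells its FPKM was 64.5, 54.2 and 75.3 in the WT libraries and 64.4, 73.1 and 81.2 in those labelled Pten-null, so its level went against the label (log2 change 0.18, limma adjusted p = 0.455). In CD38high prepro-B cells Pten fell from 78.5 ± 10 to 55.4 ± 2.70 FPKM (SD, n = 3; log2 −0.49 ± 0.13 SE, limma adjusted p = 0.0356). That Pten call was lost without WT replicate 2 (adjusted p = 0.0621) or 3 (0.122), and without Pten-null replicate 1 (0.0985) or 2 (0.106). It was also lost with no filter (0.0707), without trend (0.0545) and in a fit of the compared libraries alone (0.0542). The labels do not give the deleted part of the gene, so a gene-level FPKM does not check the deletion, and the CD38low libraries are called labelled Pten-null. Cd38, the surface enzyme used for the sort, rose from 6.46 ± 3.41 in CD38low to 38.8 ± 13.2 FPKM in CD38high WT cells (log2 2.46 ± 0.33, limma adjusted p = 0.00249). It rose from 2.88 ± 0.632 to 25.4 ± 7.53 FPKM in libraries labelled Pten-null (log2 2.73 ± 0.33, limma adjusted p = 0.000438).

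**Figure D1:**
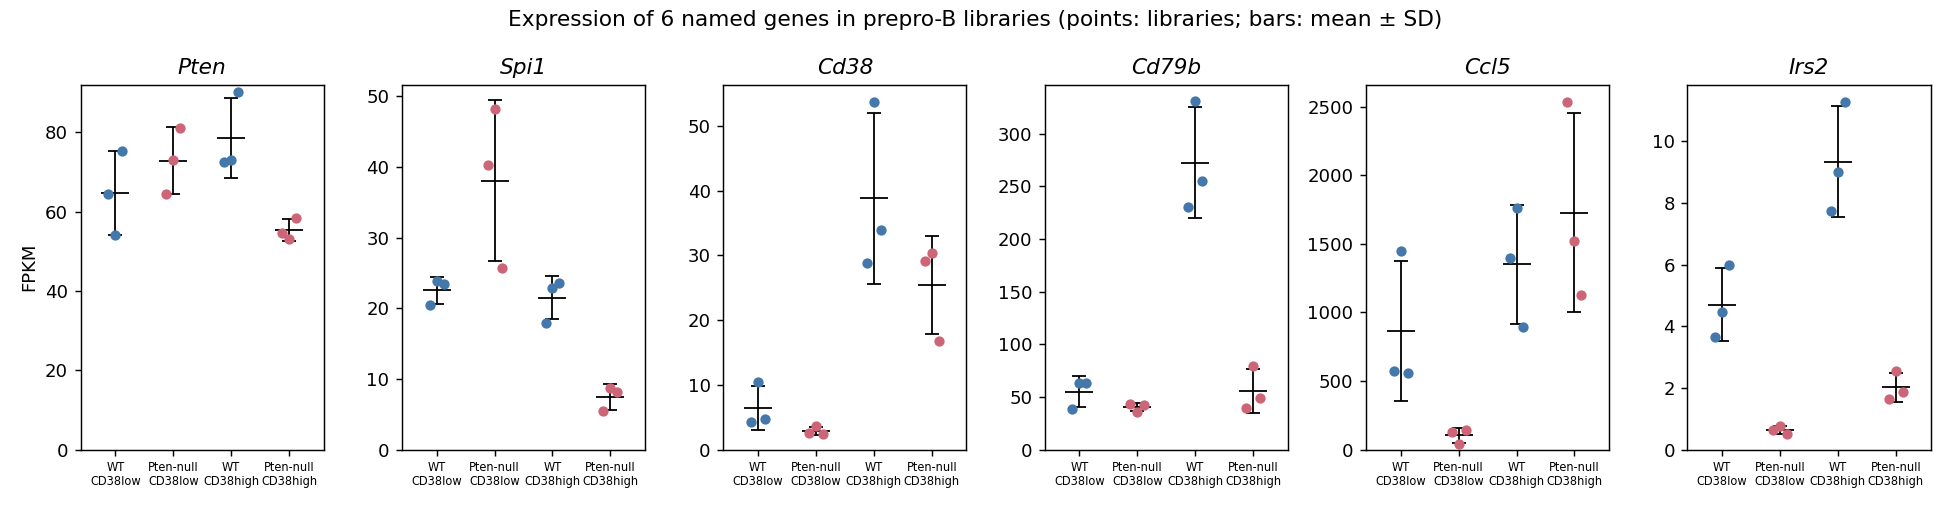
FPKM of Pten, Spi1, Cd38, Cd79b, Ccl5 and Irs2 in the 12 bulk RNA libraries, with 1 point per library and the mean and SD per group (n = 3). Spi1 averaged 38 in CD38low and 7.46 in CD38high libraries labelled Pten-null, while the WT means were 22.6 and 21.5.

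The first comparison asked what differs in CD38low prepro-B cells labelled Pten-null. Bulk values average over all cells of a gate. In each RNA comparison a shift in the mix of cells was not separated from a change within cells. Among cell cycle genes the mitotic kinases Aurka (23.2 ± 1.83 to 39.4 ± 4.42 FPKM) and Plk1 (30.6 ± 5.31 to 56.3 ± 5.63, SD, n = 3) rose. The cell cycle inhibitor Cdkn1a rose as well (9.97 ± 2.87 to 48.1 ± 7.42, log2 2.19 ± 0.23 SE). FOXO target genes fell, among them the insulin receptor substrate Irs2 (4.71 ± 1.20 to 0.635 ± 0.139; log2 −1.79) and the homing receptor Sell (604 ± 41.8 to 267 ± 31.1; log2 −1.18). The chemokine Ccl5, which cytotoxic lymphocytes express, fell from 862 ± 509 in WT to 104 ± 56.4 in the labelled libraries (log2 −3.09 ± 0.53). Igll1, the surrogate light chain of early B cells, rose (log2 2.27 ± 0.41), while the B cell coreceptor Cd19 fell (22.5 ± 8.10 to 4.32 ± 2.42). Spi1 was 22.6 ± 1.89 in WT and 38 ± 11.4 in the labelled libraries and did not pass (log2 0.69 ± 0.22, limma adjusted p = 0.0832). Without CD38low replicate 3 labelled Pten-null the Spi1 log2 change was 0.94 and passed (adjusted p = 0.0187). The other alternatives gave an adjusted p of 0.0514 to 0.26.

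By list, 11 of 24 proliferation genes rose and 0 fell (20 rose when adjusted over the list alone), with Tyms and Rrm2, enzymes of nucleotide supply, at log2 0.62 and 0.61; the camera adjusted p was 4.49e-14, and the adjusted p = 0.145 with an estimated correlation. Of 20 FOXO targets 8 fell and 0 rose (11 fell adjusted over the list alone), including the quiescence factor Klf2 (log2 −0.93) and the egress receptor S1pr1 (log2 −1.05); this list passed in both forms of camera (adjusted p = 3.8e-08 and 0.0286). Of 18 NK and innate lymphoid markers 4 fell (6 adjusted over the list alone), such as the cytokine receptor Il18r1 (log2 −1.35; camera adjusted p = 0.000259, adjusted p = 0.684 with an estimated correlation). Of 13 immediate-early genes 4 fell (5 adjusted over the list alone), among them Junb (170 ± 28.5 to 76.3 ± 18.2) and Btg2 (59.7 ± 5.43 to 27.9 ± 2.37; camera adjusted p = 0.000474, adjusted p = 0.256 with an estimated correlation). Of 19 glycolysis genes 4 rose (8 rose and 1 fell adjusted over the list alone), with Gapdh at 598 ± 58.9 and 970 ± 103 and Aldoa at log2 0.81. The camera adjusted p of this list was 0.00725, with adjusted p = 0.684 with an estimated correlation and 0.0675 without CD38low replicate 3 labelled Pten-null. Sterol synthesis genes passed with 2 of 20 higher (3 adjusted over the list alone; camera adjusted p = 0.000328, adjusted p = 0.384 with an estimated correlation). The interferon list (0 of 23 called, median log2 −0.28) and the ATF4 list (3 of 13 higher, 1 lower) had camera adjusted p of 0.0171 and 0.0466, and each had an adjusted p = 0.684 with an estimated correlation. The interferon call was lost without WT CD38low replicate 1 (0.114) or CD38low replicate 3 labelled Pten-null (0.2). The ATF4 call was lost without WT CD38low replicate 2 (0.113) or 3 (0.0731), without CD38low replicate 3 labelled Pten-null (0.2), and after quantile normalization (0.0912).

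B-lineage genes moved in both directions, with 3 higher and 2 lower of 25 (4 and 6 adjusted over the list alone), and the T-lineage list had 3 higher and 3 lower of 23 (3 and 4 adjusted over the list alone). Neither list passed camera (adjusted p = 0.51 and 0.374). Of 16 SWI/SNF subunits 2 rose and 1 fell, of 15 p53 targets 1 rose and 3 fell, and of 10 dendritic cell and MHC class II genes 2 rose and 1 fell, without a camera call (adjusted p = 0.374, 0.61 and 0.809). The mature B, stem, myeloid, pDC, erythroid, basophil and stromal lists did not pass either (adjusted p = 0.105, 0.973, 0.973, 0.973, 0.973, 0.485 and 0.973). Of 8 Notch targets 2 rose, with Hes1 at 6.75 ± 0.398 and 21.1 ± 2.12 (log2 1.51), and Myc fell (46.8 ± 3.92 to 28.1 ± 3.04; log2 −0.72; camera adjusted p = 0.973). Among 24 PU.1 targets the kinase Hck rose (4.91 ± 0.828 to 13.3 ± 3.57) and 3 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.973). The largest rises outside the lists included the receptor kinase Mst1r (1.69 ± 0.529 to 20.3 ± 4.35; log2 2.99 ± 0.29), the tetraspanin Tspan9 (log2 2.77) and AA467197 (log2 3.52). The largest falls included Gimap3 (log2 −3.22), the lectin Cd209a (log2 −3.08), lymphotoxin beta Ltb (44.4 ± 18.4 to 5.23 ± 2.81) and Ctla2a (92.5 ± 27.2 to 10.4 ± 1.93; log2 −3.01 ± 0.20), whose close paralog Ctla2b moved with it, so their shares of reads are uncertain.

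Limma called 1157 of 13738 genes, 517 higher and 640 lower (3374 at an unadjusted p under 0.05), and named values here have limma adjusted p between 9.39e-05 and 0.0085 unless given. The count was 630 in a fit of the 6 compared libraries alone, 514 without WT CD38low replicate 2, 563 without WT replicate 3, 505 without replicate 1 labelled Pten-null and 518 without replicate 2 labelled Pten-null. With the replicate block it was 1772. Of the 63 named genes called, 37 held in every fit with 1 library left out; each gene given here with a verb of change did.

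The same question in CD38high prepro-B cells gave lower levels of most B-lineage list genes, although the list call was lost with an estimated correlation, as given below. Cd79b and Cd79a, the signalling chains of the B cell receptor, fell from 272 ± 52.6 to 55.8 ± 20.6 FPKM (log2 −2.31 ± 0.25) and from 250 ± 48.8 to 60.9 ± 19 (log2 −2.05 ± 0.30; SD, n = 3). Spi1 fell from 21.5 ± 3.04 to 7.46 ± 1.80 (log2 −1.43 ± 0.22 SE, limma adjusted p = 0.00344), and so did its relative Spib (265 ± 62.1 to 113 ± 21.1). The killer-lectin receptor Klrg1 rose from 2.92 ± 0.477 to 42.2 ± 15.2 (log2 3.40 ± 0.36) and the serine protease Tmprss6 from 0.567 ± 0.205 to 14.8 ± 4.51 (log2 3.31). The glycolytic enzyme Aldoa rose from 126 ± 13.7 to 265 ± 25.3 (log2 1.07 ± 0.14).

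Of 25 B-lineage genes 19 fell and 0 rose (20 fell adjusted over the list alone), among them the adaptor Blnk (72.4 ± 16.7 to 28 ± 9) and the surrogate light chain gene Vpreb2 (log2 −1.45); camera gave an adjusted p of 1.9e-13 and the adjusted p = 0.131 with an estimated correlation. Of 15 mature B cell genes 6 fell (8 adjusted over the list alone), including the immunoglobulin segments Ighd (44.8 ± 6.45 to 9.71 ± 2.27) and Ighm (1470 ± 259 to 489 ± 102). Its camera adjusted p was 1.08e-05, with adjusted p = 0.131 with an estimated correlation. Of 24 PU.1 targets 8 fell and 0 rose (11 adjusted over the list alone), with the kinases Syk (log2 −0.85) and Btk (log2 −1.31), which did not pass in the fit of the compared libraries alone. Its camera adjusted p was 0.00016, with adjusted p = 0.238 with an estimated correlation. Of 12 stem and progenitor genes 6 fell (7 adjusted over the list alone), for example the ETS factor Erg (2.82 ± 0.165 to 0.741 ± 0.3; camera adjusted p = 2.89e-05, adjusted p = 0.142 with an estimated correlation).

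Of 20 FOXO targets 11 fell and 1 rose (12 and 1 adjusted over the list alone), led by the chemokine receptor Ccr7 (13.6 ± 1.62 to 2.74 ± 1.09; log2 −2.0), Irs2 (9.34 ± 1.80 to 2.02 ± 0.480) and S1pr1 (log2 −1.48); the list passed in both forms of camera (adjusted p = 5.07e-07 and 0.0496). Of 24 proliferation genes 9 rose and 0 fell (16 adjusted over the list alone), with cyclin Ccne1 at log2 0.93 (camera adjusted p = 1.23e-09, adjusted p = 0.145 with an estimated correlation). Of 19 glycolysis genes 11 rose and 0 fell in both counts, the second adjusted over the list alone, with Gapdh at log2 0.89, Pgk1 at 0.81 and Pfkp at 0.91 (camera adjusted p = 5.28e-05, adjusted p = 0.336 with an estimated correlation).

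The NK list passed in the opposite direction to the CD38low comparison, with 2 of 18 higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.00149, adjusted p = 0.496 with an estimated correlation). Its granzyme Gzmb rose from 39.2 ± 10.8 to 227 ± 55.7 (log2 2.51 ± 0.52, limma adjusted p = 0.0125), a call lost without WT CD38high replicate 3 or Pten-null CD38high replicate 1. T-lineage genes moved apart, with Lat (21.2 ± 1.08 to 51.4 ± 5.55), Thy1 (130 ± 27.9 to 356 ± 109) and Bcl11b (log2 1.36) higher and Cd3e lower (16.1 ± 7.03 to 3.29 ± 2.52; log2 −2.04). Cd3e did not pass in the fit of the compared libraries alone. Of 23 T-lineage genes 3 rose and 1 fell (4 and 2 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.177). The plasmacytoid dendritic cell (pDC) and myeloid lists passed with 1 and 2 members lower (camera adjusted p = 0.0168 and 0.0142), and had adjusted p = 0.519 and 0.608 with an estimated correlation. The pDC call was lost without WT CD38high replicate 1 (0.222) or Pten-null CD38high replicate 1 (0.0933). The myeloid call was lost without WT CD38high replicate 2 (0.216) or Pten-null CD38high replicate 1 (0.0559) or 3 (0.0751). Sterol synthesis genes passed with 1 higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.0184, adjusted p = 0.466 with an estimated correlation), and lost the call without WT CD38high replicate 3 (0.0907) or Pten-null CD38high replicate 3 (0.166). ATF4 targets passed with 2 higher, in both counts, the second adjusted over the list alone (camera adjusted p = 0.0494, adjusted p = 0.466 with an estimated correlation). They lost the call without WT CD38high replicate 2 (0.189), without Pten-null CD38high replicate 2 (0.0828) or 3 (0.14), and after quantile normalization (0.0934). Basophil and mast cell genes did not pass (adjusted p = 0.179) unless the replicate block was used (0.0467).

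Limma called 1618 genes, 790 higher and 828 lower (3778 at an unadjusted p under 0.05). The count was 697 in the fit of the 6 compared libraries, 869 and 821 without WT CD38high replicates 2 and 3, and 803 and 914 without Pten-null CD38high replicates 1 and 2. Of 56 named genes called, 41 held in every fit with 1 library left out, and values named here without a p have limma adjusted p between 0.00017 and 0.0115. The genotype comparisons of both fractions share no libraries. Together they had 189 genes higher in both, against 29.7 for independent lists, 196 lower in both, against 38.6, and 21 called in opposite directions. Same-numbered libraries of the 2 fractions deviate together, so some agreement above these values is expected with no shared genotype effect. How much was not estimated, so the excess alone is not taken as evidence of a shared effect.

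CD38high and CD38low prepro-B cells of WT mice were compared to describe what the sort separates. B cell transcripts that rose in the CD38high fraction included Cd19, at 22.5 ± 8.10 in CD38low and 140 ± 19.4 in CD38high cells (log2 2.64 ± 0.37), Ms4a1 (CD20) at 2.08 ± 0.143 and 24.4 ± 6.12 and the IgM receptor gene Fcmr at 4.09 ± 1.21 and 42.1 ± 11.9. The progenitor antigen Cd34 fell (12.4 ± 1.5 to 2.49 ± 0.905; log2 −1.97 ± 0.29), and so did the growth factor receptor Csf1r (7.10 ± 1.12 to 1.75 ± 0.967). Spi1 was 22.6 ± 1.89 and 21.5 ± 3.04 and did not pass (log2 −0.07 ± 0.22, limma adjusted p = 0.91).

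Of the B-lineage list 10 rose and 2 fell (17 and 3 adjusted over the list alone; camera adjusted p = 4.99e-07, adjusted p = 0.304 with an estimated correlation), and 9 of 15 mature B cell genes rose (11 adjusted over the list alone; adjusted p = 9.79e-11, adjusted p = 0.0555 with an estimated correlation). Among the latter the lambda segments Iglc1, Iglc2 and Iglc3 rose by log2 5.07, 4.14 and 4.13, although reads shared between these near-identical segments make each value uncertain, and the plasma cell gene Jchain rose from 2.03 ± 1.75 to 162 ± 98.2. Markers of other cells rose beside them, namely the T cell genes Cd3e (0.402 ± 0.283 to 16.1 ± 7.03) and Trac (2.38 ± 1.56 to 30.3 ± 14.5) in a list with 3 of 23 higher (adjusted p = 0.000789, adjusted p = 0.382 with an estimated correlation), and the macrophage complement genes C1qa (log2 2.85) and C1qc (log2 2.69). The myeloid list leaned the other way, with 0 of 27 higher and 4 lower (1 and 4 adjusted over the list alone), Csf1r among the latter, and did not pass (camera adjusted p = 0.0548). The erythroid list passed (adjusted p = 0.000789, adjusted p = 0.21 with an estimated correlation) with 0 of 14 members called. Sterol synthesis genes fell, 4 lower and 1 higher of 20 (7 and 1 adjusted over the list alone), with the demethylase Cyp51 at log2 −0.80 and the desaturase Scd1 at log2 2.48 (camera adjusted p = 7.98e-06, adjusted p = 0.21 with an estimated correlation). Of 12 stem genes 3 fell (5 adjusted over the list alone; camera adjusted p = 0.0133, adjusted p = 0.382 with an estimated correlation, and 0.0537 without WT CD38high replicate 1). Of the FOXO targets 4 rose (9 rose and 1 fell adjusted over the list alone), including Btg1 (153 ± 36 to 330 ± 42; camera adjusted p = 0.000789, adjusted p = 0.18 with an estimated correlation).

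Limma called 638 genes, 432 higher and 206 lower (2530 at an unadjusted p under 0.05). The balance depends on scaling: quantile normalization gave 401 higher and 402 lower, and the trimmed mean 402 and 279. The count was 415 with no filter, 1013 with an animal block within genotype, and 238, 335 and 275 without WT CD38low replicate 1, WT CD38low replicate 3 and WT CD38high replicate 2. Named values have limma adjusted p between 0.000409 and 0.00776. Stromal and endothelial genes did not pass (camera adjusted p = 0.0579) unless the replicate block was used (0.0485).

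The CD38 fractions of the libraries labelled Pten-null were compared in the same way. Pten-null CD38high replicate 3 stood apart from its group on the first principal component of the RNA libraries (6.11 against 39.92 and 39.34). Spi1 fell from 38 ± 11.4 in CD38low to 7.46 ± 1.80 FPKM in CD38high cells (log2 −2.19 ± 0.22 SE, limma adjusted p = 0.000264; n = 3). Ccl5 rose from 104 ± 56.4 to 1730 ± 726 (log2 4.16 ± 0.53) and Gzmb from 23.4 ± 17.8 to 227 ± 55.7 (log2 3.53 ± 0.52). The progenitor antigen Cd34 fell from 25.6 ± 9.53 to 0.887 ± 0.484, the granule enzyme Mpo from 296 ± 182 to 15.7 ± 9.04, and the lymphoid DNA polymerase Dntt from 164 ± 38.4 to 20.2 ± 5.12. Pten was 72.9 ± 8.36 and 55.4 ± 2.70 (limma adjusted p = 0.0556, and 0.01 with the replicate block). The Pten difference also passed in the fit of the compared libraries (0.0431), with the animal block (0.0371), after trimmed-mean scaling (0.0337) or quantile normalization (0.0262), and without CD38low replicate 1 labelled Pten-null (0.049).

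Of 18 NK markers 14 rose and 0 fell, in both counts, the second adjusted over the list alone; examples were the interleukin receptor chain Il2rb (236 ± 109 to 860 ± 205) and the receptor Klrd1 (214 ± 102 to 620 ± 33.4; camera adjusted p = 2.48e-07, adjusted p = 0.271 with an estimated correlation). Of 23 T-lineage genes 15 rose and 2 fell (17 and 2 adjusted over the list alone), with the kinases Itk (log2 1.79) and Zap70 (log2 1.74) and the receptor segment Trbc1 (81.2 ± 39.4 to 438 ± 107; adjusted p = 3.67e-05, adjusted p = 0.271 with an estimated correlation). Of 24 PU.1 targets 9 fell and 1 rose (10 and 1 adjusted over the list alone), with Csf1r at log2 −2.56, Ncf1 at log2 −1.56 and the phosphatase Ptprc, which rose, at log2 1.41 (adjusted p = 0.014, adjusted p = 0.472 with an estimated correlation). Of 12 stem genes 6 fell and 0 rose (8 adjusted over the list alone), including Erg (7.41 ± 0.863 to 0.741 ± 0.3) and Lmo2 (log2 −1.39; adjusted p = 3.67e-05, adjusted p = 0.271 with an estimated correlation).

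B-lineage genes went both ways, with Igll1 (74.3 ± 31.4 to 6.27 ± 2.77) lower and Cd19 (4.32 ± 2.42 to 32.4 ± 13.4) higher, 5 rising and 7 falling of 25 (6 and 8 adjusted over the list alone), and camera did not pass (adjusted p = 0.206). The mature B and pDC lists did not pass. After trimmed-mean scaling the mature B list did, with 6 higher and 1 lower (camera adjusted p = 0.049), while the pDC list had 3 higher and 5 lower (0.245). Of 20 sterol genes 10 fell and 1 rose (11 and 1 adjusted over the list alone; adjusted p = 0.000137, adjusted p = 0.271 with an estimated correlation), with the synthase Fdps at log2 −1.44. Of 27 myeloid genes 10 fell and 2 rose, in both counts, the second adjusted over the list alone (camera adjusted p = 0.014, adjusted p = 0.632 with an estimated correlation). The myeloid call was lost without CD38low replicate 2 labelled Pten-null (0.0615) and after quantile normalization (0.0553). Of 24 proliferation genes 6 fell and 0 rose (9 adjusted over the list alone; camera adjusted p = 0.0221, adjusted p = 0.606 with an estimated correlation). Of 20 FOXO targets 8 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0378, adjusted p = 0.271 with an estimated correlation, and 0.136 without Pten-null CD38high replicate 2). Of 13 immediate-early genes 7 rose, in both counts, the second adjusted over the list alone, led by Junb (log2 1.52) and Btg2 (log2 1.3; adjusted p = 0.00366, adjusted p = 0.271 with an estimated correlation). Of 15 p53 targets 7 rose and 2 fell (9 and 3 adjusted over the list alone), with Cdkn1a falling from 48.1 ± 7.42 to 11.8 ± 2.10, and the list did not pass camera (adjusted p = 0.116). Limma called 3197 genes, 1848 higher and 1349 lower (4815 at an unadjusted p under 0.05), and quantile normalization turned the balance to 1421 higher and 1767 lower. The count was 1993 without CD38low replicate 2 labelled Pten-null and 1891 without Pten-null CD38high replicate 1. Genes named with a change have limma adjusted p between 7.27e-05 and 0.00169.

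**Figure D2:**
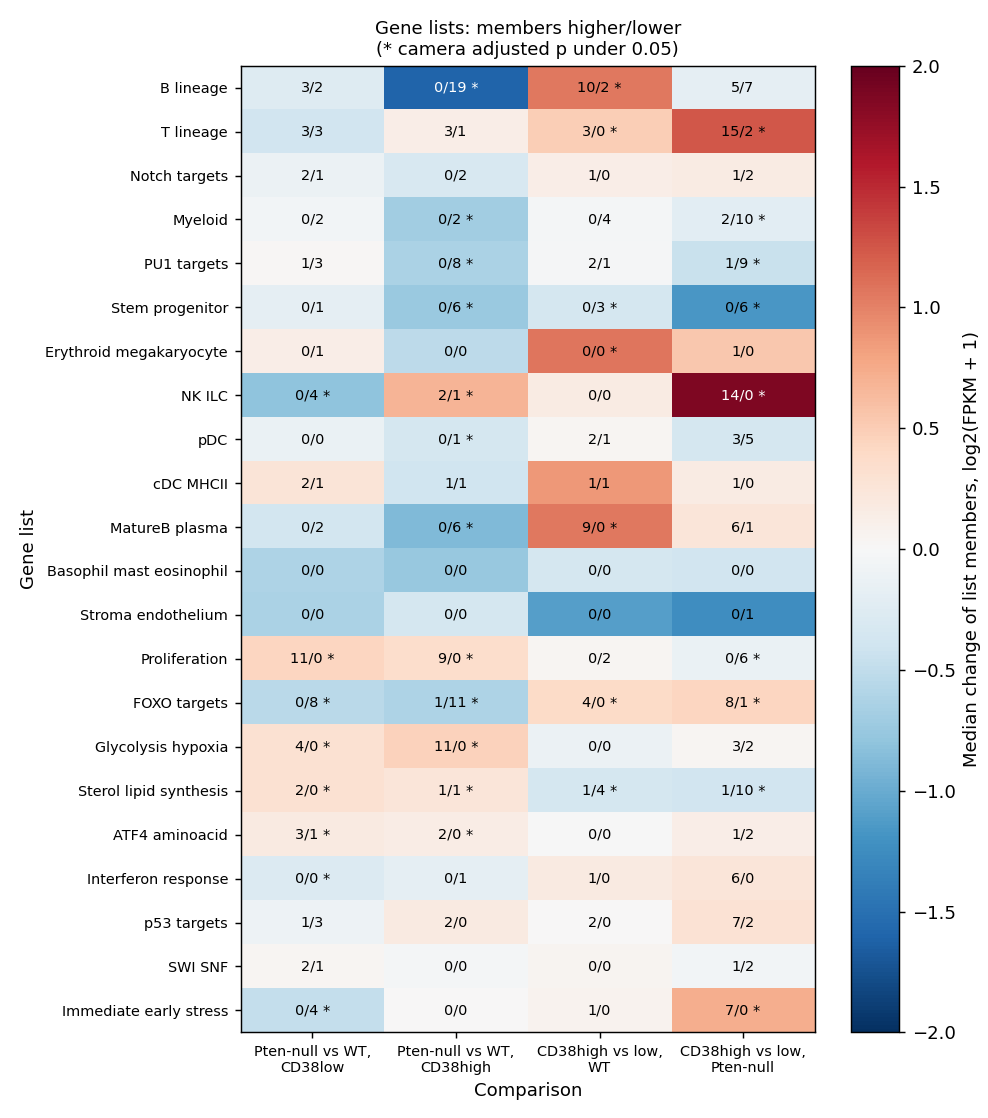
Median log2 change of the tested members of each gene list in the 4 RNA comparisons, with the numbers of members called higher and lower; an asterisk marks a camera adjusted p under 0.05 at the preset correlation. The NK list has medians of −0.80 and 0.68 in the CD38low and CD38high genotype comparisons.

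The interaction tests whether the difference between genotypes itself differs between the fractions. Spi1 had log2 values of 0.69 in CD38low and −1.43 in CD38high cells, and its interaction was −2.11 (limma adjusted p = 0.0175). It lost the call without WT CD38low replicate 2 (adjusted p = 0.0534), WT CD38high replicate 2 (0.0602) or 3 (0.0567) or CD38low replicate 1 labelled Pten-null (0.0641). Ctla2a (2.22), the Notch regulator Dtx1 (−2.22), Hck (−2.24) and Ighd (−1.64) kept their interaction calls in all 12 fits that left out a library. By list, B-lineage genes had a median interaction of −1.62, with 0 higher and 6 lower (2 and 17 adjusted over the list alone; camera adjusted p = 2.33e-10), and NK markers one of 1.64, with 1 higher (13 adjusted over the list alone; adjusted p = 3.61e-10); both lists had an adjusted p = 0.245 with an estimated correlation. PU.1 targets had 0 higher and 2 lower (1 and 8 adjusted over the list alone), a median of −0.69 and a camera adjusted p of 0.0015 (adjusted p = 0.25 with an estimated correlation). The stem list (0 called, 5 lower adjusted over the list alone), the mature B list (2 lower) and the immediate-early list (1 higher, 4 adjusted over the list alone) passed at 0.000501, 0.00445 and 0.00417, each with adjusted p = 0.245 with an estimated correlation. The SWI/SNF, pDC and T-lineage lists passed with 0 members called (7 higher and 1 lower T-lineage genes adjusted over the list alone), at 0.0204, 0.0326 and 0.0367, with adjusted p = 0.518, 0.673 and 0.613 with an estimated correlation. The SWI/SNF call was lost without WT CD38low replicate 2 (0.0578) or WT CD38high replicate 3 (0.0868). The pDC call was lost without WT CD38low replicate 3 (0.0542), WT CD38high replicate 1 (0.222), CD38low replicate 2 labelled Pten-null (0.15), or Pten-null CD38high replicate 1 (0.0723) or 2 (0.0789). The T-lineage call was lost without WT CD38low replicate 1 (0.053) or 2 (0.0868), WT CD38high replicate 2 (0.132) or 3 (0.1), or Pten-null CD38high replicate 3 (0.0632). With the replicate block the T-lineage and pDC lists did not pass (0.0859 and 0.0599) and the myeloid list did (0.0247, against 0.0732). With fry, which does not compare a list with other genes, 0 of these 9 interaction lists passed. The count of 195 genes (105 positive, 90 negative; 2170 at an unadjusted p under 0.05) is the least stable here. It was 41 with no filter, 123 with a pseudocount of 0.1, 99 without trend and 403 with the replicate block. Without WT CD38low replicates 1, 2 and 3 it was 39, 24 and 61, and without WT CD38high replicates 1, 2 and 3 it was 129, 27 and 27. Without CD38low replicates 1, 2 and 3 labelled Pten-null it was 20, 39 and 469, and without Pten-null CD38high replicates 1, 2 and 3 it was 36, 53 and 389.

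ATAC-seq asked whether loss of Pten alters accessibility along the path from stem cells to prepro-B cells. In HSC 4655 regions were gained in both Pten-null libraries and lacking in both WT libraries, and 1180 were lost. In LMPP the numbers were 3619 and 1066, and in CLP 3579 and 2642. With the same number of peaks per library they were 2337 and 2272 in HSC, 2404 and 1594 in LMPP and 3196 and 3049 in CLP. At a −log10 q of at least 5 the balance turned in HSC (1736 and 2242) and CLP (1846 and 3651), and it turned in CLP without WT replicate 2 (5802 and 8541). HSC libraries held 74346 ± 2118 peaks in WT and 85428 ± 359 in Pten-null mice (SD, n = 2). The lowest −log10 q of a deposited list was 1.83 and 2.07 in WT HSC and 1.31 and 1.36 in Pten-null HSC. The Pten-null lists thus reached weaker peaks. Gained HSC regions with the highest peak significance near list genes lay within the body of the endothelial cadherin gene Cdh5 (chromosome 8, 104100746 to 104101705, mm10) and 224 bp from Nkg7, a cytotoxic granule gene (chromosome 7, 43438470 to 43438984). A region 45665 bp from the homeobox gene Hoxa9, its nearest list gene, was lost (chromosome 6, 52176920 to 52177432). Genes outside the lists were not considered in naming regions and may lie closer.

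In LMPP gained regions lay in the bodies of Hck (chromosome 2, 153128452 to 153128892) and of Lef1, a WNT-pathway factor of lymphoid cells (chromosome 3, 131147301 to 131147790), and 1854 bp from the stem cell regulator Mecom (chromosome 3, 30511613 to 30512229). Another region in the body of Hck was lost (chromosome 2, 153115780 to 153116098), so this gene had changes in both directions. In CLP 4 of the 5 leading gained regions near list genes had a T-lineage gene as the nearest list gene. They were in the body of Itk (chromosome 11, 46372271 to 46372843) and 18634 bp from it (46306141 to 46306514), in the body of Cd247 (chromosome 1, 165816341 to 165816748) and 13815 bp from Cd4 (chromosome 6, 124850414 to 124850878). Lost CLP regions included a pair in the body of Lef1 (chromosome 3, 131153882 to 131154284 and 131154614 to 131154959). The counts of gained and lost regions near T-lineage list genes did not differ by Fisher's exact test (two-sided) in any of these comparisons after adjustment over 154 tests.

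In CD38low prepro-B cells 2173 regions were gained and 777 lost (1585 and 1176 with the same number of peaks per library). WT replicate 1 held 65225 peaks, and without it 2354 regions were gained and 4290 lost, so the balance rests on that library. Regions in the bodies of Dtx1 (chromosome 5, 120690351 to 120691059) and of the B-lineage factor Pax5 (chromosome 4, 44709077 to 44709569) were lost, and regions in the body of Zbtb16, a factor of innate lymphocytes (chromosome 9, 48786921 to 48787375), and 8572 bp from Lmo2 (chromosome 2, 103990450 to 103990913) were gained. In CD38high cells 1902 regions were gained and 1888 lost (2086 and 1538 with the same number of peaks). This near-even balance leaned to loss without WT replicate 1, 2 or 3 (3107 and 3247, 2324 and 3327, 2437 and 2731) or Pten-null replicate 1 or 3 (2568 and 2713, 2841 and 3183). It leaned to gain without Pten-null replicate 2 (3076 and 2126). Near B-lineage genes 1 region was gained and 17 were lost there, beside Blnk, Cd79b, Dntt, Ebf1, Irf4 and Pax5 among others (Fisher's exact test against all gained and lost regions, two-sided, adjusted p = 0.00539; 6 and 20 with the same number of peaks, adjusted p = 0.0361). The strongest lay 27650 bp from Irf4 (chromosome 13, 30721007 to 30721583). A region 11989 bp from the T-lineage factor Bcl11b was gained (chromosome 12, 108016134 to 108017225), as was one 36556 bp from the NK receptor gene Klrk1 (chromosome 6, 129660459 to 129660838).

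From CD38low to CD38high cells 301 regions were gained and 3002 lost in WT, and 1751 gained and 13158 lost in cells labelled Pten-null. With the same number of peaks per library, a setting that levels gains and losses by construction, the numbers were 1018 and 1463 in WT and 4619 and 5301 in cells labelled Pten-null. CD38low libraries labelled Pten-null held 89039 ± 5846 peaks and CD38high libraries 63748 ± 4462 (SD, n = 3). Without WT CD38low replicate 1 the number lost in WT was 11664, and the number gained in cells labelled Pten-null was 3992 without CD38low replicate 2 and 2676 without CD38high replicate 2. The number gained in WT ran from 330 without WT CD38low replicate 1 to 594 without WT CD38high replicate 3. In WT a region in the body of Cd34 was lost (chromosome 1, 194938665 to 194939175) and one in the body of Cd3e gained (chromosome 9, 45009286 to 45009931). In cells labelled Pten-null 23 regions near NK markers were gained and 11 lost, with gains at Ccl5, Gzmb, Il2rb, Klrd1, Prf1 and Tbx21 among others (Fisher's exact test, two-sided, adjusted p = 4.28e-12; 57 and 5 with the same number of peaks, adjusted p = 7.45e-12). A region 2711 bp from the myeloid factor gene Cebpa was lost (chromosome 7, 35124639 to 35125220), as was one in the body of Bach2 (chromosome 4, 32536724 to 32537588). Peaks are scored as present or absent, so neighbouring regions and libraries near the calling threshold weigh as much as strong ones. Fisher's tests also count regions near the same gene as independent, so their p-values are not evidence across libraries. Leaving out any library of a group of 2 raised the counts by more than 1.5 times in HSC, LMPP and CLP, because fewer libraries then have to share a region.

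**Figure D3:**
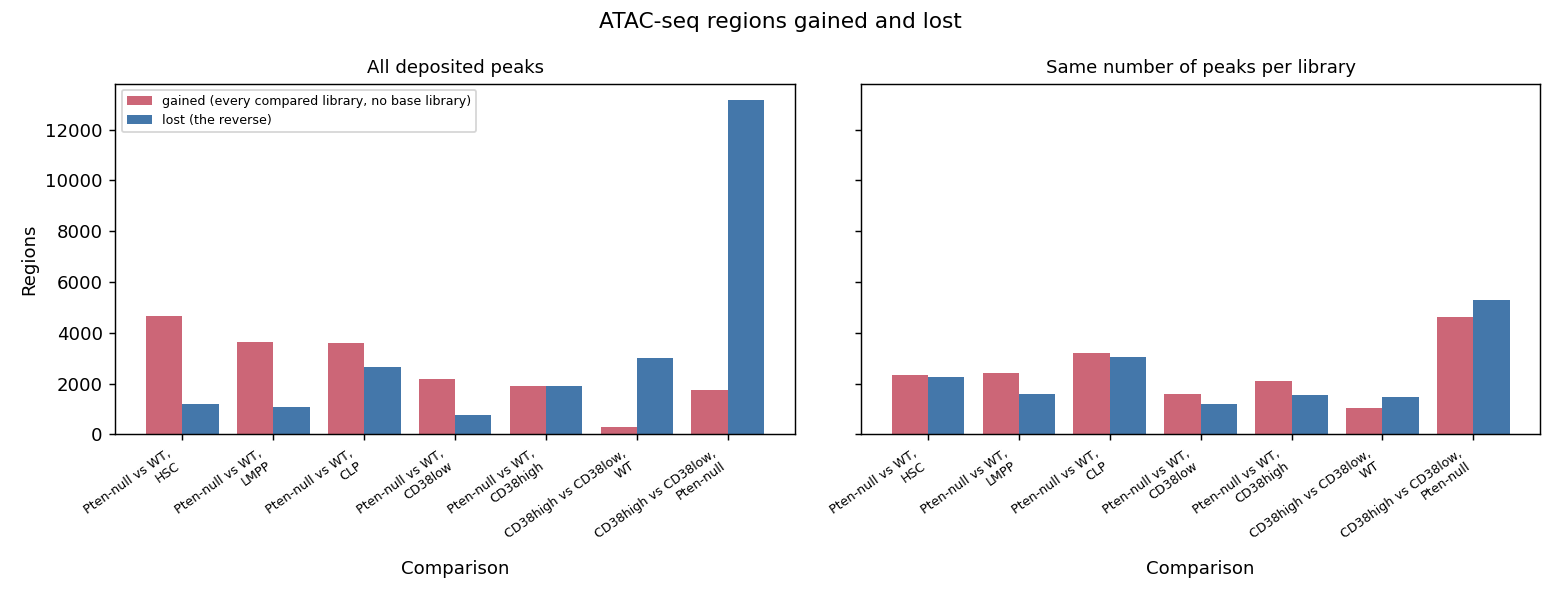
Numbers of regions gained and lost in the 7 ATAC comparisons, with all peaks and with the same number of peaks per library. The comparison of fractions labelled Pten-null has 13158 lost regions with all peaks and 5301 with equal numbers.

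At Spi1 itself (chromosome 2, 91082374 to 91115759) 0 regions within 50 kb were gained or lost between the genotypes in CD38high cells, and 1 was gained in CD38low cells (91045046 to 91045530, present in 0 of 3 WT and 3 of 3 labelled Pten-null libraries). In HSC 2 were gained, in CLP 1 was gained and 1 lost, and in LMPP 0 were gained or lost. In the fraction comparison of cells labelled Pten-null 4 regions were lost, that one and those at 91080835 to 91081737, 91084413 to 91085100 and 91086171 to 91086840, of which the last pair lie in the gene body. All 4 were present in 3 of 3 CD38low and 0 of 3 CD38high libraries labelled Pten-null. In WT they were present, in the order given, in 0, 2, 2 and 3 of 3 CD38low and in 0, 1, 0 and 2 of 3 CD38high libraries. Of all 115311 regions in the fraction comparison of cells labelled Pten-null 11.4% were lost. The losses were 4 of 21 regions within 50 kb of Spi1 and 3 of 25 within 50 kb of Pten, so they are not shown to be particular to Spi1. No region within 50 kb of Pten was gained or lost between the genotypes in HSC, LMPP, CLP or CD38high cells, with 1 gained in CD38low cells.

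**Figure D4:**
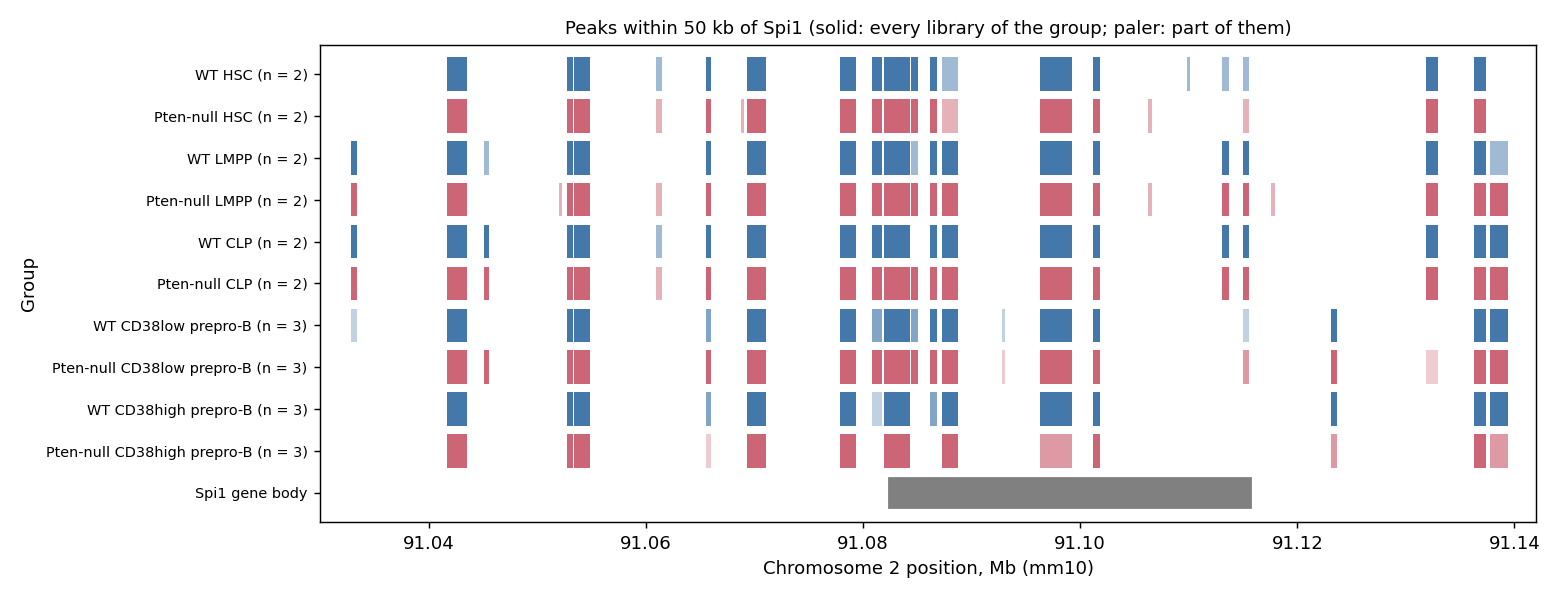
ATAC regions within 50 kb of Spi1 on chromosome 2 (mm10) by group, with the share of libraries of each group that hold a peak in the region. The gene body spans 91082374 to 91115759, and 4 regions are present in the CD38low and lacking in the CD38high libraries labelled Pten-null. Of all regions in that comparison 11.4% were lost.

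Expression was then set beside accessibility in the same fraction. Genes near regions lost in CD38high Pten-null cells were lower on balance, with 159 of 895 tested genes lower and 56 higher (camera adjusted p = 0.000838), and genes near gained regions were higher, with 138 of 955 higher and 50 lower (adjusted p = 0.00405). In CD38low cells genes near lost regions were lower, with 61 of 443 lower and 14 higher (adjusted p = 0.00156), and those near gained regions did not pass (55 higher and 31 lower of 943, adjusted p = 0.135). Between the fractions, genes near gained regions were higher in WT (14 of 209 higher, 2 lower, adjusted p = 0.000791) and in cells labelled Pten-null (387 of 997 higher, 57 lower, adjusted p = 2.22e-09), and genes near lost regions did not pass (adjusted p = 0.506 and 0.135). With the same number of peaks per library, the latter set passed in cells labelled Pten-null (385 of 1953 lower, 301 higher, camera adjusted p = 0.0236). The other 7 tests kept their side of the threshold in that setting. With an estimated correlation 0 of the 8 tests with all peaks passed. The 5 sets that passed with all peaks then had an adjusted p of 0.0606, 0.152, 0.0606, 0.07 and 0.0606 with an estimated correlation, in the order given. All 5 passed in each of the 12 fits without an RNA library.

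Single cells of 12 Pten-null populations were sorted into plates, from progenitors of the bone marrow (HPC1, HPC2, MPP, CLP, prepro-B) to thymocytes (DN1 to DN4, DP) and T cells (CD4T, CD8T). There is 1 library per population except prepro-B, so values are described without a test, and intervals cover counting error only. Spi1 reached 145 CPM (counts scaled to the library total) in HPC1, 76.4 in MPP and 55.4 in HPC2, 24.4 in CLP, and 57.7 and 54 in the prepro-B libraries. In thymic and T cell populations it was at most 2.21 CPM, with 0 counts in DN3, DP and CD8T. Cd34 went from 402 CPM in HPC1 to 71.2 in CLP and 9.12 and 5.75 in prepro-B cells, while the T-lineage factor Tcf7 was at 66.3 and 106 in prepro-B cells, 444 to 965 in the thymic populations DN1 to DP and 0.304 in CLP.

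Against CLP, the prepro-B libraries held more NK transcripts. The NK list made up 1.05% (95% Clopper-Pearson interval 1.045 to 1.053) and 0.690% (0.6871 to 0.6927) of counts in prepro-B replicates 1 and 2 and 0.0273% (0.02671 to 0.02798) in CLP. Ccl5 and Gzma, both with 0 counts in CLP, were at least 12400-fold and 12000-fold higher, and Xcl1 at least 5430-fold. The PU.1 target list made up 0.550% and 0.617% against 0.236%, and Spi1 was 2.28-fold higher (2.09 to 2.48). The pDC list made up 0.546% and 0.846% against 0.364%, with the pDC receptor Siglech 3.02-fold higher (2.95 to 3.09). B-lineage genes made up less, 0.199% and 0.217% against 0.299%, with Ebf1 at a fold of 0.492 (0.472 to 0.513) and Dntt at 0.114 (0.111 to 0.117), although Cd19 was 6.97-fold higher (4.79 to 10.5). Of the 22 lists, 8 had a higher share in both prepro-B libraries than in CLP. Among granule genes of neutrophils, Lcn2 had 0 counts in prepro-B cells and 1942 in CLP, and Ngp, with 2 counts in prepro-B cells, stood at a fold of 0.000362 (2.92e-05 to 0.000872).

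Against DN3 thymocytes, prepro-B cells held few T cell receptor transcripts. The fold was 0.0011 for Cd3g (0.00086 to 0.00139), a chain of the T cell receptor complex, and 0.00264 for the pre-T cell receptor chain Ptcra (0.00212 to 0.00326). Spi1, with 0 counts in DN3, was at least 1510-fold higher, the adaptor Tyrobp 52500-fold (20500 to 193000) and Fcer1g at least 27700-fold.

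Prepro-B wells were not alike. A share over 1% of the NK list was found in 46 of 94 wells of replicate 1 (48.9%, 38.5 to 59.5) and 31 of 95 wells of replicate 2 (32.6%, 23.4 to 43), and in 0 of 58 CLP wells, which allows up to 6.16%. Wells with over 1% of the pDC list numbered 24 (25.5%, 17.1 to 35.6) and 43 (45.3%, 35 to 55.8), 0 wells passed for both lists, and 24 and 21 passed for neither. These classes are ranges of a share and not types, with a threshold chosen after the data were seen; 29 and 18 wells lay between 0.5% and 2% for the NK list and 22 and 29 for the pDC list. The prepro-B gate sets which cells were sampled, and single wells were not separated by CD38. In replicate 1 Spi1 stood at 4.64 CPM in NK wells (3.49 to 6.04), 64.4 in pDC wells (57.9 to 71.4) and 130 in the rest (122 to 138). In replicate 2 it stood at 9.31, 38.4 and 113. These sums rest on few wells, and the medians of Spi1 over wells were 0.588, 5 and 8.39 CPM in replicate 1 and 0, 2.23 and 68.3 in replicate 2. In replicate 2 a single well held 67 of the 86 Spi1 counts of the NK wells, which stood at 2.09 without it, and 4 of 43 pDC wells held 457 of 530. Among wells of the rest, 4 held 679 of 1065 Spi1 counts in replicate 1 and 4 held 670 of 1208 in replicate 2. Of the rest, 7 of 24 and 5 of 21 wells held over 1% of the B-lineage list, and the median share was 0.157% and 0.11%. Summed Igll1 was at 607 and 565 CPM in the rest against 13.9 and 11 in NK wells, but 4 wells held 4714 of 4987 and 5401 of 6064 of its counts. Over wells of the rest the median Igll1 was 16 and 13.2 CPM, against 13.3 and 9.58 over NK wells. Ccl5 was at 3810 and 3770 CPM in NK wells, yet also at 107 and 80.4 in pDC wells, with counts in every kept prepro-B well, so a low count there is not evidence of expression.

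**Figure D5:**
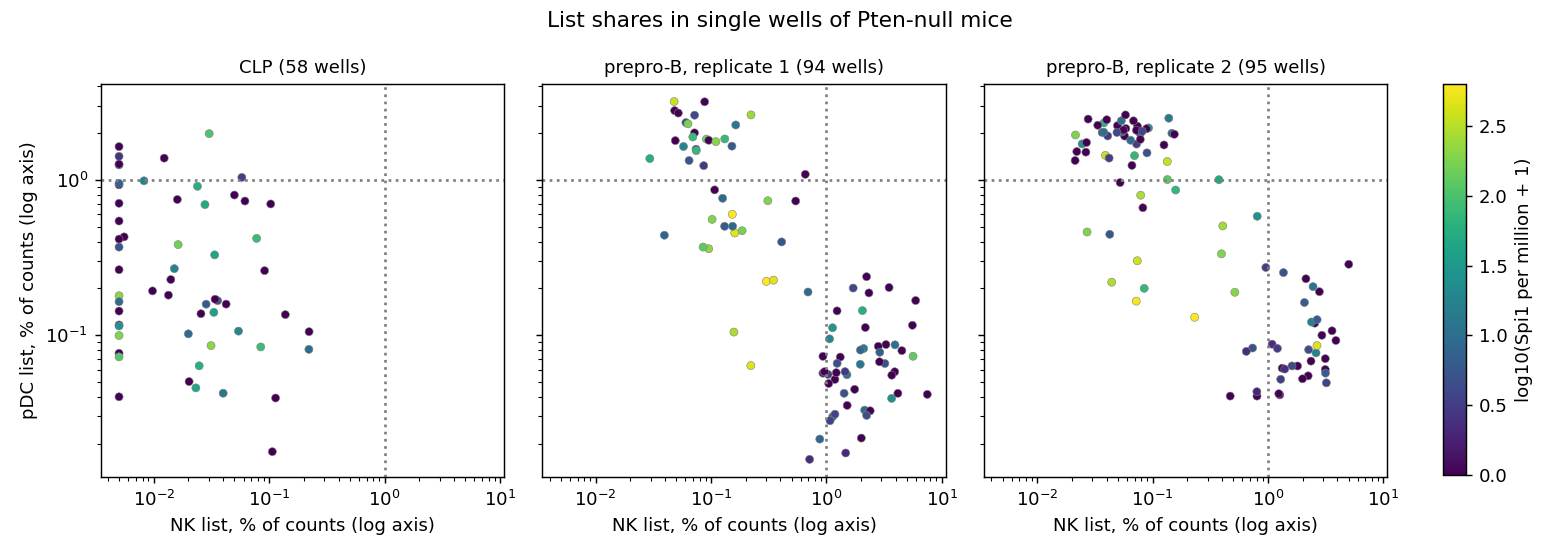
Share of counts in the NK list against the pDC list for each kept well of CLP and of prepro-B replicates 1 and 2, on log axes, coloured by Spi1 CPM. Wells with the lowest NK shares, not only those with 0 NK counts, are drawn together at the left edge. No well lies over 1% for both lists, and Spi1 has a median of 0.588 and 0 CPM over the NK wells of replicates 1 and 2, with a highest value of 130.5 and 448.6.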

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

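Each weighing test given here, the well profiles among them, was chosen after the result it bears on was seen.

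The 22 genes below were picked out because the difference between genotypes itself differed between the CD38 fractions in limma's interaction test, from 184 named genes. The interaction was negative, on the log2 scale, for Myl4 (−3.65), Igll1 (−2.88), Cd79a (−2.58), Mst1r (−2.48), Hck (−2.24), Dtx1 (−2.22), Spi1 (−2.11), Cd79b (−1.91), Dntt (−1.79), Ighd (−1.64), Scd1 (−1.53), Myo18b (−1.42), Hes1 (−1.30) and Ighm (−1.23). It was positive for Phactr3 (3.10), Tmprss6 (2.82), Ctla2b (2.53), Klrg1 (2.43), Ctla2a (2.22), Serpina3g (2.17), Klrd1 (1.85) and Junb (1.28). Ctla2a, Dtx1, Hck and Ighd passed in each of the 12 fits without a library, and the other 18 lost the call in at least 1 fit. Of 100 splits of the libraries, the real one included, 2 gave as many genes as the real 195, with 211 as the highest of the others. Single outlying values were not tested in groups of 2 or 3 libraries.

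In the fractions labelled Pten-null, Spi1 was lower and NK markers were higher in CD38high than in CD38low cells. A larger part of cells with the NK profile as the whole cause of the Spi1 fall is argued against: 222 genes as low in NK wells as Spi1, with a mean FPKM of at least 5 in CD38low cells labelled Pten-null, had a median log2 change of −0.873 (lower quartile −1.522, 127 lower and 3 higher) against −2.19 ± 0.22 for Spi1, and the profiles of pDC wells and of wells with neither profile had medians of −0.18 and −0.42. Such a part may account for the rise of the NK markers and some of the Spi1 fall: 102 tested genes high in NK wells but outside the NK list had a median log2 change of 1.445, with 62 higher and 1 lower, and NK wells had 4.64 and 9.31 Spi1 CPM against 130 and 113 in wells with neither profile (medians over wells 0.588 and 0 against 8.39 and 68.3, with 679 of 1065 and 670 of 1208 counts of the latter in 4 wells), although the wells were not separated by CD38 and NK cells were not counted per fraction here. Lower Spi1 within CD38-expressing cells outside the NK profile cannot be told apart from fewer Spi1-rich cells among them, since the ratio of Spi1 in such wells with and without a Cd38 count was 0.991 (0.878 to 1.12) and 0.94 (0.852 to 1.04) and the gate was set on the protein, with Cd38 mRNA counted in 9 and 27 such wells. In the CD38high genotype comparison the same 222 genes had a median log2 change of −0.376, with 55 lower and 2 higher. Of 107 tested genes of the NK profile, 13 were higher and 1 lower there. In the CD38low genotype comparison 0 were higher and 27 lower. The mix of cells may thus differ between the genotypes as well, and its part in those results was not tested. A direct effect of Pten loss on Spi1 stays open and was not tested.

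Gains outnumbered losses in Pten-null HSC, and losses outnumbered gains from CD38low to CD38high cells labelled Pten-null. At equal peak numbers the ratio of gained to lost regions was 1.03 in HSC and 0.871 between the fractions. That setting levels both directions by construction, so it cannot tell the number of peaks called from a difference in accessibility itself. The deposited HSC lists reached down to a −log10 q of 1.83 and 2.07 in WT but 1.31 and 1.36 in Pten-null mice. At a −log10 q of at least 5, HSC libraries held 61827 and 65192 peaks in WT and 61379 and 61266 in Pten-null mice. Losses then outnumbered gains (1736 gained, 2242 lost), so the excess of gains in HSC rests on weaker peaks. Between the fractions losses still outnumbered gains at that threshold (1837 gained, 12212 lost). Both explanations stay open, but in HSC the excess of gains is not taken as evidence of more accessible chromatin.

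Pten was not lower in the CD38low libraries labelled Pten-null. Exchanged labels are argued against by the FOXO target list, whose mean lay below all WT CD38low libraries in 3 of 3 libraries labelled Pten-null. A transcript of the deleted allele that is still counted cannot be told apart from incomplete deletion, as the lowest Pten level among the single-cell populations was 25.2 CPM (CD4T) and the deleted part is not given in the labels.

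For the other comparisons the splits of the libraries are too few for a share under 0.05. For RNA, 1 of 10 splits gave as many genes in each comparison, with a real count and a highest other of 1157 and 1 for the CD38low genotype comparison, 1618 and 2 for CD38high, 638 and 1 for the WT fractions and 3197 and 1 for the fractions labelled Pten-null. For ATAC regions, 1 of 3 splits gave as many in HSC (5835 real, 3830 highest other) and in CLP (6221 and 4308), and 2 of 3 in LMPP (4685 and 5391). In the prepro-B comparisons 1 of 10 splits did (2950 and 2459 for CD38low, 3790 and 729 for CD38high, 3303 and 2358 for the WT fractions, 14909 and 722 for the fractions labelled Pten-null).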

How the results depend on the processing

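The trimmed-mean scaling, quantile normalization, animal block within genotype and, for the link of regions and genes, the estimated correlation, replicate block and left-out libraries were chosen after the data were seen. Where no reason is given for a shift, the cause was not tested.

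With no filter on low values the WT fraction comparison called 415 genes and the interaction 41. In a fit of the compared libraries alone the CD38low and CD38high genotype comparisons called 630 and 697. The interaction count was 123 with a pseudocount of 0.1 and 99 without trend, and the animal block gave 1013 genes for the WT fractions. Leaving out each library gave 505 to 978 genes for the CD38low genotype comparison, 803 to 1523 for CD38high, 238 to 531 for the WT fractions, 1891 to 3279 for the fractions labelled Pten-null and 20 to 469 for the interaction. With an estimated correlation 2 of 110 list tests passed in place of 45, and 0 of 8 sets of genes near regions in place of 5. Without a library the numbers were 44 to 48 lists and 5 of 8 sets. Scaling also added list calls. After trimmed-mean scaling the mature B list passed between the fractions labelled Pten-null (camera adjusted p = 0.049). The glycolysis list passed between the WT fractions with that scaling (0.0453). After quantile normalization the SWI/SNF list passed in the CD38high genotype comparison (0.0269).

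The replicate block, a fit that pairs libraries by number, gave 403 interaction genes in place of 195, and 1772 in place of 1157 for the CD38low genotype comparison. There the correlations of same-numbered libraries were 0.175, 0.0231 and 0.25, and 5 of 6 libraries correlated best with their own number. The other comparisons join these libraries through the same numbers, so pairing is unsettled here and rests on the data alone. Cd38 did not pass in this comparison (limma adjusted p = 0.133) but did with the block (0.0272). The block changed the call of 11 of 306 named results, 3 lost and 8 gained. Of the 110 list tests it gained the basophil list in the CD38high genotype comparison (0.0467 from 0.179) and the stromal list between the WT fractions (0.0485 from 0.0579). In the interaction it gained the myeloid list (0.0247 from 0.0732) and lost the T-lineage (0.0859 from 0.0367) and pDC lists (0.0599 from 0.0326), and it changed no other call. Where the numbers paired the libraries, the block gave 2322 genes in place of 1618 for the CD38high genotype comparison, 947 in place of 638 for the WT fractions and 3842 in place of 3197 for the fractions labelled Pten-null. Peak presence and single-cell shares come from no test and had no paired fit.

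For ATAC regions, a −log10 q of at least 5 gave 1736 gained and 2242 lost in HSC, 508 lost in LMPP, 1846 gained in CLP and 423 lost in CD38low cells. The same number of peaks per library gave 2337 gained and 2272 lost in HSC, 2404 gained in LMPP, 1176 lost in CD38low cells, 1018 gained and 1463 lost between the WT fractions, and 4619 and 5301 between the fractions labelled Pten-null. Counts rise by construction when a library is left out, since fewer libraries have to share a region. Gained regions then numbered 8157 to 14685 in HSC, 6970 to 11572 in LMPP, 5802 to 13060 in CLP, 2354 to 4048 in CD38low and 2324 to 3107 in CD38high cells, 330 to 594 between the WT and 1900 to 3992 between the fractions labelled Pten-null. Lost regions numbered 2940 to 5181, 3069 to 6347, 4152 to 8541, 1003 to 4290, 2126 to 3327, 3531 to 11664 and 13897 to 17645, in the same order.

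Among named genes and sets called in the main fit, 0 reversed under any setting. Results without a call were not checked for a reversal. Spi1 between the WT fractions, for example, went from a log2 of −0.075 to 0.042 without WT CD38high replicate 1. Of 298 results, 242 kept their side of the threshold with no filter, 273 without trend, 283 and 288 with pseudocounts of 0.1 and 5, 282 after quantile normalization and 286 after trimmed-mean scaling. Without a library 413 of 1920 results lost a call, and the 1920 include results with no call in the main fit. With fry, 20 of the 45 list calls were lost, all 9 of the interaction among them, and 6 other lists passed. Single-cell shares moved beyond their counting interval in 262 of 286 cases as a mean of per-well shares and in 257 without mitochondrial and haemoglobin genes, and in 2 with other well filters. The motif test and its alternatives were not run, as no genome sequence was used here, and alternatives for counts do not apply to FPKM. The FPKM values carry no read depth, so no detection limit can be given for genes near 0, and intervals of single-cell shares cover counting error only.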

Other observations

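The comparison of sex-linked genes given here was made after the data were seen, and the populations are described without a test, as each has 1 library.

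Among the Pten-null thymic populations, genes of the T-lineage were already high in cells sorted as DN1. Ptcra stood at 335 CPM in DN1, 326 in DN2, 554 in DN3 and 211 in DN4, Tcf7 at 444, 500, 541 and 756, and the progenitor antigen Cd34 had 0 counts in DN1. The T-lineage list made up 0.654% of counts in DN1, 0.802% in DN3, 1.01% in DN4 and 2.37% in DP. Cd4 and Cd8a followed the sort, with Cd4 at 389 CPM in DP, 226 in CD4T and 4.91 in CD8T, and Cd8a at 2120, 21.3 and 725. The granule protease Gzma was at 397 CPM in DN1, 788 in DN4 and 1350 in CD8T, with 0 counts in DP and CD4T.

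In bone marrow, HPC1 held immunoglobulin transcripts, with Igkc at 12300 and Ighm at 10100 CPM, while Igkc was at 3.94 in HPC2. The mature B and plasma cell list made up 2.78% of HPC1 counts and passed 1% in 16 of its 60 wells, with the threshold taken over from the prepro-B wells. Immediate-early genes made up 1.14% of counts in MPP, 1.02% in HPC1, 0.785% in HPC2 and 0.693% in CLP, against 0.0623% to 0.151% in the thymic and T cell populations. The organ, the preparation and the population cannot be separated in these libraries.

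The prepro-B libraries differed in sex-linked transcripts. Xist, the RNA of the inactive X chromosome, was at 272 CPM in replicate 1 and 0.444 in replicate 2, while Y-linked genes were at 1.64 and 301. All 95 kept wells of replicate 2 had Y-linked counts. The other single-cell libraries had Xist at 126 to 712 CPM and Y-linked genes at no more than 4.76, so the comparison of replicate 2 with CLP and DN3 also crosses sex.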
